A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

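The samples were 3 RNA-seq libraries of cytoplasmic RNA from Saccharomyces cerevisiae BY4741 in mid-log growth in YPD: 1 from unselected total RNA, 1 from RNA selected with oligo(dT) Dynabeads and 1 from RNA treated with RiboMinus. The deposited values are RPKM, made by the authors and given to 2 decimals for 5293 ORFs in each library. Per the submitters' processing notes, Bowtie2, TopHat2 and the genome sacCer3 were used. Their roles and versions, the read counter and the annotation are not given in the sources used here. The sum of RPKM times coding length, and the spacing of low values, fit reads per kilobase of coding sequence without the stop codon and per 1e6 reads in the listed ORFs. That unit was inferred from the values. All 5293 ORF names were matched to the R64 annotation, 203 of them after a hyphen was restored, and coding lengths, GC content and positions come from there. The 2 columns of per-sample values from other libraries were not used here.

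Low RPKM values times coding length fall on whole multiples of a single step in each library, which gives the number of reads assigned to the listed ORFs. It was 4452591 for the unselected, 6467517 for the poly(A)-selected and 1317754 for the RiboMinus library. Of the values under 100 reads, 99.9%, 99.6% and 99.9% lay within 0.1 read of a whole number. The median ORF had 271, 474 and 87 reads, and 43, 24 and 89 ORFs were listed at 0. A count of 0 allows up to 3 reads, which is 0.674, 0.464 and 2.28 RPKM for an ORF of 1 kb. The interval of a named gene's ratio is the 95% Clopper-Pearson (exact binomial) interval of its share of the reads of the libraries compared. It covers counting error only, and reads without molecular identifiers are not independent molecules.

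ORFs with a mean RPKM over the libraries of at least 1 were kept, which left 5199 and removed 94. The ratio of each comparison is the log2 of RPKM plus 0.5 in both libraries, minus its median over the ORFs kept. The medians removed were 0.24 log2 for poly(A)-selected against unselected, 0.076 for RiboMinus against unselected and 0.11 for poly(A)-selected against RiboMinus. An ORF counts as higher or lower at 2-fold, which is a rule of size and not of significance. Members of a gene list are counted as higher or lower at 1.5-fold. What counting error alone gives was found from 100 draws in which every ORF kept the same level in both libraries. The variance each library adds alone was worked out from the variances of the 3 comparisons. Spearman's rho and medians per quintile relate the ratios to coding length, coding GC content and the longest run of A.

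A total of 21 gene lists was fixed, and 18 of them were compared with 10000 random lists of the same size, matched by decile of mean expression. A list stood apart when its median lay outside the central 95% of the random lists. The lists were cytosolic ribosomal proteins of the large and of the small subunit, mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, glycolysis and fermentation, TCA cycle, respiratory chain and ATP synthase, proteasome, chaperones, histones, cell wall proteins, ergosterol synthesis, amino acid synthesis, cyclins, RNA polymerase subunits, glucose-repressed genes and meiosis genes. The files list 33 of the 81 large-subunit names, 25 of the 56 small-subunit names, 13 of the 21 glycolysis names, 4 of the 10 histone names and 29 of the 39 cell wall names, so those medians describe part of each family. ORFs of the rDNA locus and strain markers were read gene by gene. The mitochondrial genome list, LEU2 and URA3 were not analysed here. The interval of a list or quintile is the 95% order-statistic interval of its median. The interval of a slope is the central 95% of 2000 bootstrap draws over ORFs. The named genes are the 10 highest and 10 lowest ORFs of each comparison with the unselected library, and the 5 highest and lowest of the other comparison, among those with a mean RPKM of at least 10 and above 0 in both libraries. For each list they are the 3 most abundant members and the highest and lowest members of each comparison, and the 10 most abundant ORFs are named as well.

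The comparisons, lists, thresholds and naming rule were chosen before the data were examined. The alternatives were a pseudocount of 0.1 or 2, no filter, a mean RPKM of at least 10, no centring, an expression-weighted centre, removal of the trend with expression or with coding length by a running median over 10% of the ORFs, a threshold of 1.5-fold, an SD from the median absolute deviation, and random lists matched on coding length. Random lists matched on coding length or GC content also numbered 10000, and list calls under the other alternatives rest on 2000 random lists each. Alternatives chosen after the data were seen were removal of the trend with GC content, at least 100 reads in every library, random lists matched on GC content, and ORFs that overlap no other ORF.

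The method was tested on simulated data in which 200 ORFs, drawn from those with a mean RPKM of at least 10, differed between libraries. Detection of changes at lower levels was not tested. In each of the 3 simulated comparisons the recovered reads equalled the simulated ones for 100% of the ORFs. A 4-fold higher level was called in 100% of 50 ORFs in each comparison. A 4-fold lower level was called in 100% of 50 ORFs against the unselected library and in 98% for poly(A)-selected against RiboMinus. Of the intervals, 92.5%, 94.5% and 96% held the simulated ratio in the order poly(A)-selected against unselected, RiboMinus against unselected and poly(A)-selected against RiboMinus. In that order 29 of 4988, 82 of 4994 and 71 of 4993 unchanged ORFs were called. A list shifted by 0.4 log2 was found at 0.39, 0.39 and 0.38. A slope on log2 coding length of -0.6 was found as -0.593, -0.587 and -0.606. After the trend with length was removed, a rho of -0.106, -0.071 and -0.074 was left. An SD of 0.5 log2 added to the first-named library was found as 0.51, 0.59 and 0.51. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.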

Results

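The cells were Saccharomyces cerevisiae BY4741, a laboratory haploid of mating type a, taken in mid-log growth in YPD, a rich glucose medium. Cytoplasmic RNA was sequenced in 3 libraries that differ in how the RNA was prepared. The unselected library was made from total RNA. The poly(A)-selected library was made from RNA captured on Dynabeads, magnetic beads that carry oligo(dT) and bind poly(A) tails. The RiboMinus library was made from RNA from which rRNA had been removed with RiboMinus, a kit of probes that bind rRNA. Each preparation has 1 library, so no difference has a replicate check and no p-value is given. The intervals of named genes cover counting error only. Those of list medians, quintile medians and slopes describe the spread across ORFs, which are not independent replicates. A ratio is a centred log2 ratio, which places an ORF relative to the median ORF of the same comparison. It is taken after 0.5 is added to each RPKM, which understates the differences of ORFs with low values.

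Of the 10 most abundant listed ORFs of the unselected library, 6 belong to glycolysis and fermentation. PDC1, which encodes pyruvate decarboxylase, had the highest value at 20602 RPKM. The aldolase gene FBA1 followed at 14477 RPKM and the cell wall protein gene CCW12 at 11814 RPKM. Other glycolytic and fermentative genes were close behind, with ADH1 at 11495 RPKM, the pyruvate kinase gene CDC19 at 11426 RPKM, PGK1 at 11093 RPKM and GPM1 at 10196 RPKM. The ribosomal protein genes RPL39 and RPL28 had 7088 and 6915 RPKM. The 10 most abundant ORFs took 14.6% of the reads of the unselected library. ADH1 shares 18.8% of its 30-mers with other ORFs, so its value can include reads from its paralogs.

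The levels of strain markers were read against the strain label. The mating type a genes MFA1 and MFA2, which encode a-factor, had 715 and 788 RPKM in the unselected library. STE2, the receptor for alpha-factor, had 429 RPKM, and BAR1, the protease that degrades alpha-factor, had 217 RPKM. Of the alpha-specific genes, STE3 had 6.53 RPKM, MF(ALPHA)1 had 1.81 RPKM and MF(ALPHA)2 had 0.62 RPKM in the same library. MF(ALPHA)1 had 5.62 RPKM in the poly(A)-selected library and 15.3 RPKM, from 10 reads, in the RiboMinus library, where MFA1 and MFA2 had 330.3 and 346 RPKM. MET17, which is deleted in BY4741, had 0.84 RPKM in the unselected library, 2.21 RPKM in the poly(A)-selected library and 1.71 RPKM in the RiboMinus library. Its annotated ORF overlaps YLR302C, so reads of either gene can fall there. HIS3 had 113 RPKM in the unselected library. The his3 allele of this strain lacks an internal part of the ORF, and the remaining parts can still give reads.

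The comparison of the poly(A)-selected with the unselected library asked whether capture by oligo(dT) alters the relative levels of mRNAs. Long ORFs were lower after selection and short ORFs were higher. The lower ORFs included FAS1, the beta subunit of fatty acid synthase, TRA1, a large subunit of the SAGA and NuA4 acetyltransferase complexes, CHC1, the clathrin heavy chain, and GLT1, glutamate synthase. Many short ORFs of ribosomal proteins of the cytosol and of mitochondria were higher. Several enzymes of glycolysis were lower than other ORFs of their length, and so was DED1, an RNA helicase of translation initiation.

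Of the 5199 ORFs kept, 343 were at least 2-fold higher and 449 at least 2-fold lower in the poly(A)-selected library. Counting error alone gave on average 12.2 ORFs higher and 10.3 lower. The counting interval excluded the centre for 321 of the 343 higher ORFs and for 439 of the 449 lower ORFs. The SD of the ratio across ORFs was 0.72 log2, against 0.19 from counting error alone. Across genes, which are not independent replicates, Pearson's r between the libraries was 0.932 and Spearman's rho was 0.910. As deposited, the median ORF was 0.24 log2 higher in the poly(A)-selected library, and this shift was removed. Without centring, 705 ORFs were at least 2-fold higher and 249 lower, so 73.9% of the calls were higher rather than 43.3%.

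Relative to the median ORF, the poly(A)-selected library had 5.44-fold less DED1, with a ratio of -2.44 and an interval of -2.53 to -2.37. DED1 lies on chromosome XV from 722911 to 724725 in the R64 genome and had 679.8 RPKM in the unselected library against 147 after selection. FAS1 (chromosome XI, 100671 to 106826) had a ratio of -2.20 with an interval of -2.24 to -2.17, from 956 and 245 RPKM. TRA1 (chromosome VIII, 302761 to 313995), whose coding sequence of 11232 nt is among the longest of the genome, had a ratio of -2.27. CHC1 had -2.34, GLT1 had -2.18 and CDC39, the scaffold of the CCR4-NOT deadenylase complex, had -2.19. Among ORFs with a mean of at least 10 RPKM, the lowest ratios belonged to SWC7, a subunit of the SWR1 chromatin remodelling complex, at -2.80, and RRG8, a gene needed to keep the mitochondrial genome, at -2.73. SWC7 rests on 10 reads after selection and RRG8 on 19. YBR238C, a gene linked to mitochondrial function, had -2.29.

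Among the higher ORFs, SRP21, a subunit of the signal recognition particle, had a ratio of 1.72 with an interval of 1.53 to 1.93. SRP21 (chromosome XI, 212495 to 212998) had 113 RPKM in the unselected library and 439.8 after selection. MGT1, a DNA repair methyltransferase, had a ratio of 1.78 and RMP1, a subunit of RNase MRP, had 1.69. The highest ratio at that level, 2.48, belonged to YIR018C-A, a short ORF of unknown function with 18 reads in the unselected library. The short ORFs MIN6 and RSO55 had ratios of 1.91 and 1.81, from 9 and 16 reads in the unselected library.

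The higher ORFs had a median coding length of 420 nt and the lower ORFs 3051 nt, against 1248 nt for the ORFs kept. Of 434 ORFs of at least 3000 nt, 226 were at least 2-fold lower and 0 higher. Of 860 ORFs under 600 nt, 258 were higher and 20 lower. Spearman's rho of the ratio with coding length was -0.759 across genes, against 0.166 with coding GC content and -0.293 with the longest run of A. Within quintiles of coding length the rho with GC content lay between -0.102 and 0.054. The rho with the longest run of A was positive in each of those quintiles, from 0.031 to 0.163. The quintile of shortest ORFs had a median ratio of 0.76 (interval 0.73 to 0.79) and the quintile of longest ORFs -0.77 (interval -0.80 to -0.74). When the trend with length was removed, 60 ORFs were at least 2-fold higher and 157 lower.

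**Figure D1:**
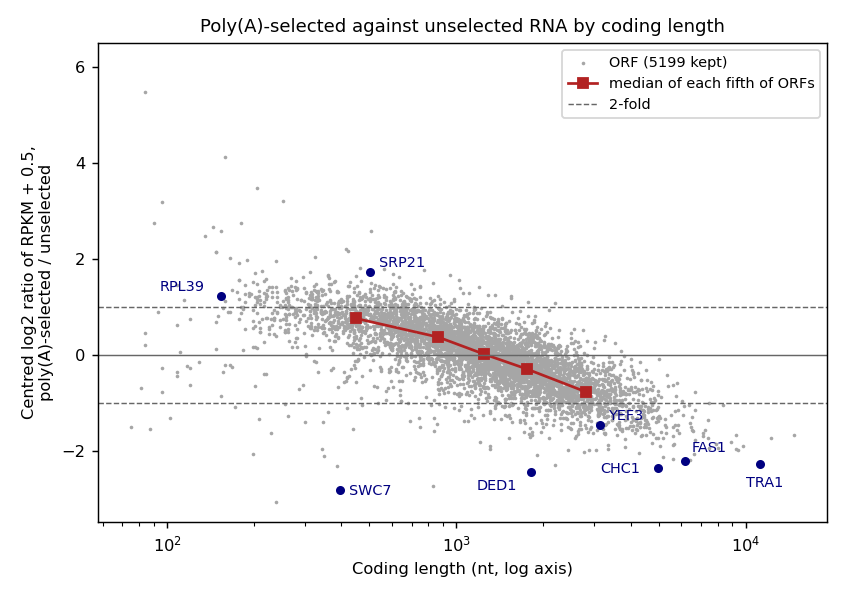
Each point is an ORF, with its coding length in nt on a log axis and its centred log2 ratio of the poly(A)-selected to the unselected library. The median of the quintile of shortest ORFs was 0.76 and that of the longest was -0.77, and DED1 at -2.44 lies far under ORFs of its length.

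Large-subunit ribosomal proteins of the cytosol had a median ratio of 0.65 over 33 listed ORFs, with 20 at least 1.5-fold higher and 0 lower. That median was at percentile 99.9 of 10000 random lists matched on expression. RPL37B had 1.35, RPL39 1.22 and RPL28 0.76, while RPL5 was lower at -0.39. RPL37B shares 11.3% of its 30-mers with other ORFs. Small-subunit proteins had a median of 0.71 over 25 ORFs, at percentile 99.8, with 13 higher and 1 lower. RPS29A had 1.34 and RPS12 0.95, and RPS28B was the lower member at -0.64. Mitochondrial ribosomal proteins had a median of 0.56 over 71 ORFs, above all 10000 random lists, with 33 higher and 1 lower. MRPS16 had 1.61 and RSM19 1.24, and NAM9, an exception with a longer ORF, had -0.61. These lists have short ORFs, with median coding lengths of 363, 390 and 711 nt, and among random lists matched on length their medians were at percentiles 12.7, 42.5 and 77.1.

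Glycolysis and fermentation had a median of -0.70 over 13 listed ORFs, with 7 at least 1.5-fold lower and 0 higher. This was at percentile 0.12 of lists matched on expression and 0.01 of lists matched on length. Against the RiboMinus library the same list had a median of -0.23, with 5 ORFs lower and 3 higher. There it did not stand apart matched on expression, at percentile 6.16, or on length, at 24.7. Matched on GC content it did, at percentile 0.43. PFK2, a subunit of phosphofructokinase, had -1.98, PGI1 -1.36, CDC19 -1.27, PDC1 -0.82 and PGK1 -0.70. TPI1, with a short ORF, was higher at 0.46, as was FBA1 at 0.20. Translation factors had a median of -0.38 over 38 ORFs, at percentile 0.04, with 16 lower and 6 higher. The elongation factor gene YEF3 had -1.46, and SUI1, a short initiation factor gene, had 1.01. Matched on length, the translation factors were at percentile 3.47. Amino acid synthesis had a median of -0.19 over 74 ORFs, at percentile 0.33 matched on expression. Matched on length it was at percentile 3.70, which is inside the central 95%. Without centring the median was 0.045, still low at percentile 0.2 matched on expression. In that list LEU1, an isomerase of leucine synthesis, had -1.17 and MET14, the kinase of sulfate assimilation, had 0.88.

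RNA polymerase subunits spanned a wide range, with a median of 0.51 at percentile 97.1. The largest subunits were lower, with RPO21 of RNA polymerase II at -2.12 and RPA190 of RNA polymerase I at -1.73, and the small subunit RPA34 was higher at 1.16. The proteasome list had a median of 0.40 at percentile 84.7. Its small subunit SEM1 had 1.45, the large base subunit RPN1 had -1.02, and the large adaptor ECM29 had -1.86. The TCA cycle had a median of -0.26 at percentile 4.31, with KGD1 at -1.97 and ACO1 at -1.31. The chaperones had a median near 0 at percentile 35.7, with 8 of 21 at least 1.5-fold lower and 2 higher, among them the mitochondrial SSC1 at -1.61 and HSP10 at 1.21. The 4 listed histone ORFs had a median of 0.63 at percentile 85.5.

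The comparison of the RiboMinus with the unselected library asked whether removal of rRNA alters the relative levels of mRNAs. Cell wall protein mRNAs were lower after RiboMinus treatment, among them CCW12, one of the most abundant mRNAs of the unselected library. Of the genes of the acidic ribosomal stalk proteins, RPP2A, RPP1B and RPP2B were lower, while RPP1A had a ratio of only -0.35. The histone genes HTB1, HTB2 and HHO1 were lower as well. ORFs rich in GC were lower and ORFs poor in GC were higher. Higher ORFs included RUB1, a ubiquitin-like modifier, and POP8, a subunit of RNase P and RNase MRP.

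In the RiboMinus library 252 ORFs were at least 2-fold higher and 298 at least 2-fold lower. Counting error alone gave on average 28.0 higher and 47.1 lower, with 1317754 reads in this library against 6467517 after oligo(dT) selection. The interval excluded the centre for 211 of the higher ORFs and 251 of the lower ORFs. The SD was 0.66 log2, against 0.33 from counting error alone. Across genes, Pearson's r was 0.939 and Spearman's rho was 0.929. The median shift that was removed was 0.076 log2.

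CCW12 lies on chromosome XII from 369697 to 370098 and had 11814 RPKM in the unselected library against 1759 in the RiboMinus library. Its level relative to the median ORF was 7.08-fold lower, with a ratio of -2.82 and an interval of -2.92 to -2.73. NCW1, another small cell wall protein gene (chromosome XIII, 511315 to 511569), had a ratio of -2.95 with an interval of -3.40 to -2.54, from 1061 and 145 RPKM. RPP2A (chromosome XV, 254297 to 254617) had -2.64 with an interval of -2.82 to -2.47, from 4021 and 678 RPKM. FIT3, a cell wall mannoprotein that takes part in iron uptake, had -2.64. SNC1, a vesicle SNARE of the secretory pathway, had -2.44 from 11 RiboMinus reads and STF1, a protein that binds the inhibitor of the ATP synthase, had -2.57 from 5. Among ORFs with a mean of at least 10 RPKM, the lowest ratios were those of YLR297W at -3.68 and SPO24 at -3.11, which rest on 4 and 13 RiboMinus reads. TIR3, a cell wall mannoprotein gene at -2.76, rests on 2 RiboMinus reads.

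Among the higher ORFs, POP8 (chromosome II, 185998 to 186474) had a ratio of 1.84 with an interval of 1.52 to 2.19, from 80.5 and 306 RPKM. RUB1 had 1.80 with an interval of 1.47 to 2.15, from 136 and 503 RPKM. FLX1, the mitochondrial FAD carrier, had 1.84, SYM1, a mitochondrial inner membrane protein, had 1.80, and DAL3, an enzyme of allantoin breakdown with 19 RiboMinus reads, had 1.93. MRX7, a small mitochondrial protein, had 2.12, with 18 reads in the unselected and 25 in the RiboMinus library. MGT1 had 1.98, so it was higher than in the unselected library after both treatments. RPC17, a subunit of RNA polymerase III, had 1.73.

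The higher ORFs had a median coding GC content of 38.4% and the lower ORFs 43.7%, against 39.7% for the ORFs kept. Spearman's rho of the ratio with GC content was -0.378 across genes. It was 0.050 with coding length, but the ORFs called in either direction were short. The higher ORFs had a median coding length of 579 nt and the lower ORFs 637.5 nt, against 1248 nt for the ORFs kept. Of 860 ORFs under 600 nt, 134 were higher and 138 lower. At the same RPKM a short ORF has fewer reads, so its counting error is larger. How many of these short-ORF calls counting error gives was not worked out. Of 434 ORFs of at least 3000 nt, 0 were higher and 0 lower. The quintile of ORFs with the least GC, 26.5% to 37.4%, had a median ratio of 0.29. The quintile with the most, 42.7% to 59.6%, had -0.39 (interval -0.45 to -0.33).

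**Figure D2:**
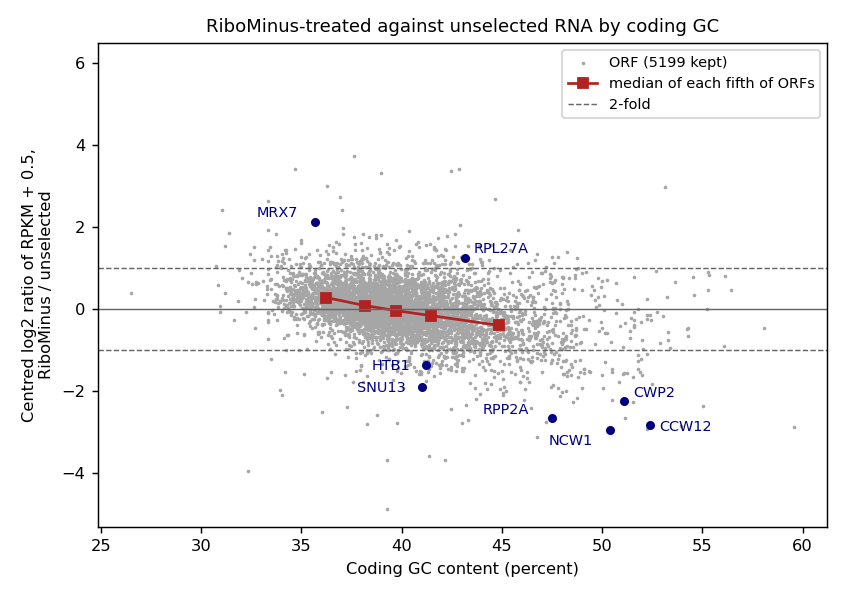
Each point is an ORF, with its coding GC content in percent and its centred log2 ratio of the RiboMinus to the unselected library. The median of the quintile with the least GC was 0.29 and that of the quintile with the most was -0.39, and CCW12 at -2.82 lies under both.

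Cell wall proteins had a median ratio of -0.74 over 29 listed ORFs, with an interval of -1.30 to -0.39, and no random list matched on expression was as low. In this list 17 ORFs were at least 1.5-fold lower and 1 higher. CWP2 had -2.23, PLB2 -0.78 and ECM33 -0.58, while TIR2, with 10 RiboMinus reads, was the higher member at 0.93. The 4 listed histone ORFs had a median of -1.29 at percentile 0.16, and 3 of the 4 were at least 1.5-fold lower. HTB1 had -1.35, HTB2 -1.33, the linker histone HHO1 -1.26 and the variant histone HTZ1 -0.52.

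Cyclins had a median of -0.41 over 13 ORFs, at percentile 0.68, with 6 at least 1.5-fold lower and 1 higher. Over the 3 cyclins with at least 100 reads in every library the median was 0.37. PCL5 had -1.06 and CLN2 -0.76, while the mitotic cyclin CLB1 was higher at 0.88. The TCA cycle had a median of -0.45 over 16 ORFs, at percentile 0.61, with KGD2 at -1.07 and CIT2 at 0.71. Amino acid synthesis had a median of -0.23 at percentile 2.02, with 18 lower and 1 higher. CYS3, an enzyme of cysteine synthesis, had -1.65 and SHM2, a serine hydroxymethyltransferase, had -1.15. Matched on GC content, the cyclins were at percentile 0.29, the TCA cycle at 7.52 and amino acid synthesis at 21.7. The proteasome list had a median of 0.25 at percentile 99.35, with 8 of 35 ORFs higher and 6 lower, and was at percentile 99.41 matched on GC content. It kept that call under 12 of 13 alternatives and lost it when the GC trend was removed. Its lid subunit RPN8 had 1.04 and SEM1 0.79, while the core subunit PRE7 had -0.92.

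The 58 listed ribosomal proteins of the cytosol had a median of -0.43, at percentile 0.54 of length-matched lists, with members on both sides. Of the 33 large-subunit ORFs, 16 were at least 1.5-fold lower and 7 higher, with a median of -0.47 at percentile 4.12 matched on expression and 1.93 matched on length, and at 8.70 matched on GC content. RPP1B had -2.15 and RPL5 -1.19, while RPL27A had 1.24, RPL10 0.92 and RPL28 0.80. Of the 25 small-subunit ORFs, 9 were lower and 4 higher, with a median of -0.26. That median was at percentile 34.1 matched on expression, 18.4 matched on length and 48.0 matched on GC content. Neither subunit's list stood apart matched on expression or on GC content, and the 58 together were compared with length-matched lists only. RPS26B had -1.94, while RPS22B had 1.06 and RPS12 0.90. Mitochondrial ribosomal proteins had a median of 0.027, with MRP20 at -1.93 from 13 RiboMinus reads, IMG1 at -1.82 and MRPL6 at 1.37. Of the chaperones, 9 were lower and 0 higher, with a median of -0.34 at percentile 4.92, and at 1.63 matched on length. Ergosterol synthesis had a median of -0.29 at percentile 6.70, and at 1.72 matched on length, with ERG25 at -0.95 and ERG26 at 0.86. Meiosis genes had a median of 0.28 at percentile 89.4, and at 98.04 matched on length. Matched on GC content, the chaperones, ergosterol synthesis and meiosis genes did not stand apart. Glycolysis had a median of -0.27 at percentile 29.9, with TPI1 at -1.02 and PDC1 at -0.65.

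The comparison of the poly(A)-selected with the RiboMinus library asked how the enriched libraries differ from each other without the unselected library. The medians of the ribosomal protein and histone lists were higher in the poly(A)-selected library, but not against lists matched on length. Also higher were the cell wall genes CCW12, NCW1 and CWP2, although the cell wall list as a whole, with a median of 0.38 at percentile 85.9, did not stand apart. Long ORFs such as GLT1 and UTP20, and DED1, were higher in the RiboMinus library. With 731 ORFs at least 2-fold higher in the poly(A)-selected library and 559 lower, this comparison had the most calls of the 3. Counting error alone gave on average 45.3 and 23.6. The interval excluded the centre for 680 of the higher ORFs and 535 of the lower ORFs. The SD was 0.92 log2 and Pearson's r across genes was 0.887. The median shift that was removed was 0.11 log2.

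Relative to the median ORF, CCW12 was 11.5-fold higher in the poly(A)-selected library, with a ratio of 3.53 and an interval of 3.43 to 3.62. NCW1 had 3.75. DPI8, a small ORF, had 4.17 and HUG1, an inhibitor of ribonucleotide reductase, had 3.80, with 4 RiboMinus reads and 1 RiboMinus read. RPP1B had 3.47, CWP2 3.08, ATP18 of the ATP synthase 2.89, SNU13, a protein of snoRNPs and the spliceosome, 2.78 and RPS26B 2.73. On the lower side, DED1 was 6.40-fold lower relative to the median ORF, with a ratio of -2.68 and an interval of -2.78 to -2.59. GLT1 had -2.59, FAS1 -2.28, ECM29 -2.25, RPA190 -2.25 and UTP20, a large ribosome biogenesis factor, -2.21. SWC7 at -2.75 and RRG8 at -2.46 rest on 10 and 19 reads in the poly(A)-selected library.

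The 4 histone ORFs had a median of 1.63 at percentile 99.2, and all 4 were at least 1.5-fold higher in the poly(A)-selected library, from HTZ1 at 1.25 to HTB1 at 2.28. Large-subunit ribosomal proteins had a median of 1.06, at percentile 99.99, with 23 higher and 1 lower. Small-subunit proteins had 0.86 at percentile 99.6, with 13 higher and 0 lower. Mitochondrial ribosomal proteins had 0.55, above all 10000 random lists. RNA polymerase subunits had 0.60 at percentile 98.6, with RPB11 at 2.42. Translation factors had -0.25 at percentile 0.28, and 0.10 at percentile 1.05 among ORFs with at least 100 reads in every library, with YEF3 at -1.67 and TIF3 at -0.82. Matched on length, none of these 6 lists lay outside the central 95% of random lists. With at least 100 reads in every library the RNA polymerase and mitochondrial ribosomal lists did not stand apart either, nor did RNA polymerase subunits without overlapping ORFs or small-subunit proteins with the expression trend removed. The ratio had a rho of -0.617 with coding length and of 0.381 with GC content across genes.

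**Figure D3:**
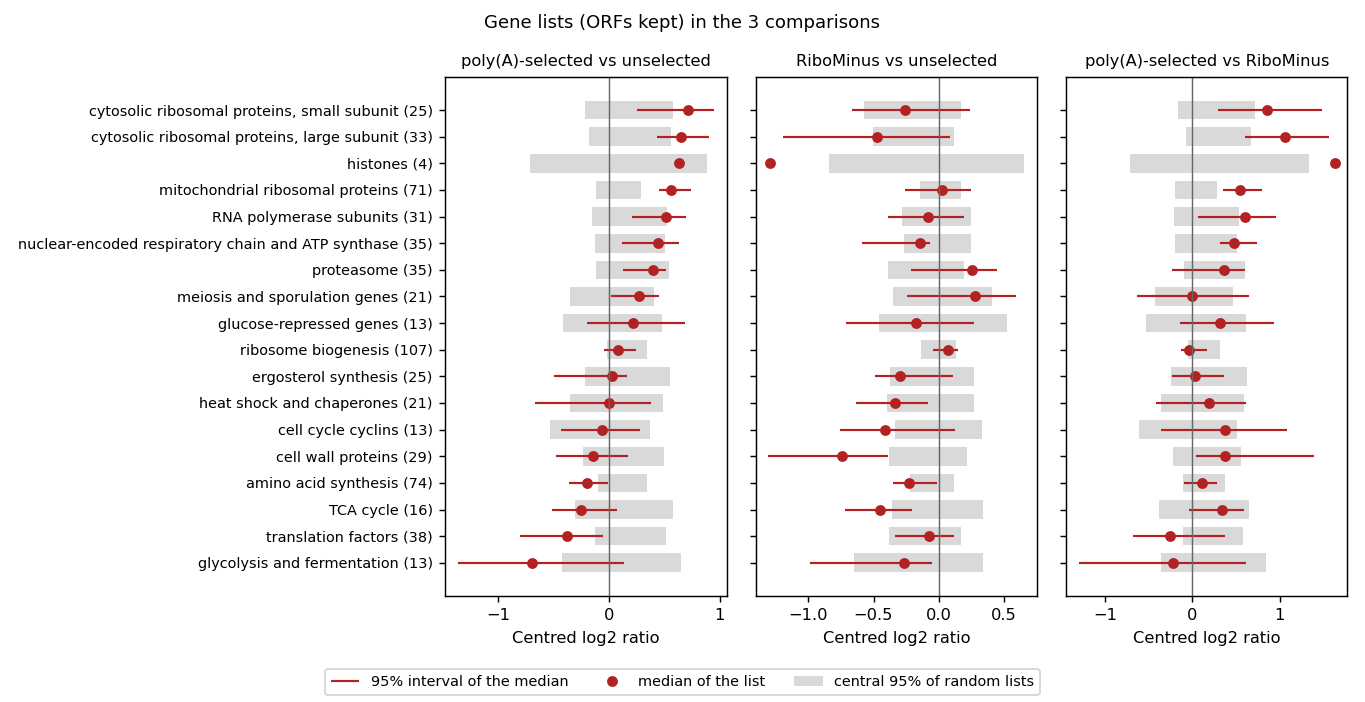
Each line holds a gene list, with its median centred log2 ratio in each of the 3 comparisons as a point, the 95% order-statistic interval as a red bar (none for the 4 histone ORFs) and the central 95% of random lists matched on expression in grey. After RiboMinus treatment cell wall proteins lie at -0.74 and histones at -1.29. Amino acid synthesis, at -0.19 after oligo(dT) selection, is 0.045 without centring and still low at percentile 0.2.

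In each comparison 6 of 18 lists lay outside the central 95% of random lists matched on expression, where chance gives 0.9. After oligo(dT) selection 3 of the 6 were higher and 3 lower, and after RiboMinus treatment 1 was higher and 5 lower. The number depends on the matching. Matched on coding length, 6 lists lay outside after oligo(dT) selection, 10 after RiboMinus treatment and 1 for poly(A)-selected against RiboMinus. Matched on GC content, the numbers were 10, 4 and 6. The comparisons share libraries and are not independent. The variance that each library adds alone, under the assumption that the libraries deviate independently, gave an SD of 0.22 log2 for the unselected library, 0.68 for the poly(A)-selected library, or 0.40 with the length trend removed, and 0.62 for the RiboMinus library. Counting error alone gave 0.15, 0.12 and 0.30. The unselected library serves both treatments as control, and with 1 such library the controls cannot be split. The covariance between the ratios of the treatments was 0.0487 across genes, against 0.0217 from counting error alone. After both treatments 81 ORFs were at least 2-fold higher, where independent ratios would give 16.6 and counting error alone 6.32. At least 2-fold lower after both were 9 ORFs, where independent ratios would give 25.7 and counting error alone 4.03. RUB1, MGT1, RPS22B and LOC1, a gene for the localisation of ASH1 mRNA and for ribosome assembly, are among the ORFs higher after both. In 32 ORFs the poly(A)-selected library was at least 2-fold higher and the RiboMinus library at least 2-fold lower, where independent ratios would give 19.7, among them RPP1B, RPL37B, ATP18, PCL5, MFA1 and MFA2. The opposite held for 2 ORFs, where independent ratios would give 21.8. The independent numbers take no account of coding length. Of 434 ORFs of at least 3000 nt, 226 were lower after oligo(dT) selection and 0 were called after RiboMinus treatment. Of 860 under 600 nt, 258 were higher and 20 lower after oligo(dT) selection, and 134 and 138 after RiboMinus treatment. Calls can thus meet or miss through length alone, so the counts cannot show shared or opposed effects of the treatments.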

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

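Removal of the GC trend, at least 100 reads in every library, GC-matched random lists and ORFs without overlap were chosen after the data were seen. No named gene past 2-fold reversed under any alternative run. Among 495 named ratios, removal of the length trend ended 74 calls of 2-fold and added 16. Only the ratios past 2-fold had a call to lose. There were 54 list medians, and in each comparison only 6 of 18 carried a call that could be ended. Of those calls, length-matched random lists ended 11 and GC-matched ones ended 3. They added 10 and 5 calls. Where counts of 2-fold ORFs kept within 1.5 times, they ranged from 282 to 359 higher and 384 to 508 lower for poly(A)-selected against unselected, from 210 to 298 and 203 to 319 for RiboMinus against unselected, and from 631 to 856 and 439 to 608 for poly(A)-selected against RiboMinus. In that order of comparisons, a 1.5-fold threshold gave, by construction, 1058 higher and 1106 lower, 761 and 831, and 1340 and 1247. At least 100 reads in every library, which leaves 2409 ORFs, gave 209 and 177, 81 and 94, and 284 and 193. Removal of the length trend gave 60 and 157 for poly(A)-selected against unselected, 379 and 363 for poly(A)-selected against RiboMinus, and a poly(A)-selected SD of 0.40. Without centring poly(A)-selected against unselected gave 705 and 249, by construction from the shift of the median. The rho of that ratio with coding length was -0.745 with no filter, -0.792 at a mean RPKM of at least 10, -0.709 without the expression trend and -0.820 at 100 reads, where the RiboMinus rho with GC was -0.406. The cause of these shifts in rho was not tested. With the length trend removed, poly(A)-selected against unselected reversed for ribosomal proteins of the large subunit (-0.019) and small subunit (-0.11), and poly(A)-selected against RiboMinus for the small subunit (-0.013) and RNA polymerase subunits (-0.018). Amino acid synthesis was 0.045 after oligo(dT) selection without centring, by construction from the shift of the median, and still low at percentile 0.2. At 100 reads, histones, glucose-repressed genes and meiosis genes, and at a mean RPKM of 10 glucose-repressed genes, had too few ORFs for a value, cyclins after RiboMinus were 0.37 over 3 ORFs, and translation factors in poly(A)-selected against RiboMinus were 0.10 over 37 of 38 ORFs, by construction from the centre of the 2409 ORFs, and still low at percentile 1.05. Glycolysis after oligo(dT) selection and cell wall proteins and histones after RiboMinus stood apart under every list alternative run. No alternative replaced the unselected library. For poly(A)-selected against RiboMinus, glycolysis was at percentile 6.16 matched on expression, 24.7 on length and 0.43 on GC content. A deviation of the unselected library thus stays open for glycolysis. Depth limits the RiboMinus library, where 433 ORFs had under 10 reads.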

Other observations

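The tests that set the poly(A)-selected against the RiboMinus library to judge the unselected library, the GC-matched lists and the genes named as farthest from a trend were chosen after the results were seen. Matched on coding length rather than on expression, further lists stood apart after oligo(dT) selection. Ribosome biogenesis had a median ratio of 0.080 over 107 ORFs, at percentile 99.99 of length-matched lists and 17.5 of expression-matched lists. Its members ran from the large UTP20 at -1.93 to the small snoRNP protein NHP2 at 1.55. Among ORFs with at least 100 reads in every library, the farthest above the length trend was BUG1, by 1.32. The 10 farthest included the ribosome biogenesis genes NOP53, by 1.30, EBP2, by 1.26, KRI1, by 1.12, and BUD22, by 1.09. They also held IFH1, a regulator of ribosomal protein genes, by 1.27, and IMH1, SYH1, HOS4 and ARP5, which are not in that list. Glucose-repressed genes had a median of 0.22 over 13 ORFs, at length-matched percentile 99.96, and meiosis genes 0.27 over 21 ORFs, at 99.93. These are mostly low: the unselected library had 9.22 RPKM for GAL1, 9.14 for ICL1 and 0.56 for SPO11, while the invertase gene SUC2 had 74.4. Respiratory chain and ATP synthase genes had a median of 0.45, at expression-matched percentile 93.9, GC-matched percentile 99.55 and length-matched percentile 1.29, with ATP18 at 1.57 and ATP2 at -1.30. Cell wall proteins had a median of -0.14, above 0 without centring, at length-matched percentile 0.85, GC-matched percentile 1.61 and expression-matched percentile 6.63. Against the RiboMinus library, ribosome biogenesis was at length-matched percentile 85.2, meiosis genes at 71.5, respiratory chain genes at 28.8 and cell wall proteins at 94.15. These did not stand apart there, while glucose-repressed genes did, at 99.75. For the lists that did not, a deviation of the unselected library stays open. RRT15, an ORF of the rDNA locus, had 10.9 RPKM in the unselected, 28.3 in the poly(A)-selected and 8.16 in the RiboMinus library, from 9, 34 and 2 reads.

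Among the same ORFs, those farthest under the length trend after oligo(dT) selection were DED1 by -2.12, SRO9, an RNA-binding protein, by -1.92, and YBR238C by -1.76. The 10 farthest also held DHH1, an RNA helicase of mRNA decay, by -1.54, the membrane proteins PMP1 and NCE102 by -1.57 and -1.35, and the translation factors NIP1 and RLI1 by -1.35 and -1.33. After RiboMinus treatment, CCW12 lay -2.29 and RPP2A -2.14 from the GC trend, and the 10 farthest also held CWP2 at -1.76, SNU13 at -1.73, RPP1B at -1.64 and AHP1, a peroxiredoxin, at -1.52. On the other side TMH11 was farthest, at 1.87, followed by TMA19 at 1.83. The 10 farthest also held RPC17 at 1.68, SKP1, a subunit of SCF ubiquitin ligases, at 1.64, and RUB1, which modifies those ligases, at 1.76.

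Long ORFs were lower after oligo(dT) selection, and capture of only the 3' part of broken mRNAs may account for it. The ratio had a slope on log2 coding length of -0.163 under 750 nt (interval -0.26 to -0.076), -0.596 from 750 to 2000 nt, -0.608 over 2000 nt (interval -0.66 to -0.55) and -0.608 among the 174 longest ORFs, which is steeper than among short ORFs but levels off short of the inverse proportion that a fixed captured length would give, so capture of varied lengths and other losses that grow with length stay open. GC content and low expression are argued against as the whole cause, since the weakest rho with length was -0.663 within quintiles of GC and -0.479 within quintiles of expression, and so is a deviation of the unselected library, since the rho was -0.617 against the RiboMinus library. The higher ratios of cytosolic ribosomal proteins could follow from their short ORFs, because the 58 ORFs together were at percentile 17.8 of length-matched lists. No biological explanation was tested, since the labels name no difference between the libraries but the preparation.

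GC-rich ORFs were lower after RiboMinus treatment. Loss through sequence shared with rRNA is argued against, since the rho with GC was -0.379 among the 3403 ORFs that share no stretch of 12 nt with the sense strand of the main rRNA of either ribosomal subunit. Low depth is argued against by a rho of -0.406 over the 2409 ORFs with at least 100 reads in every library. A deviation of the unselected library is argued against by a rho of 0.381 for the poly(A)-selected over the RiboMinus library. Part of that rho can come from coding length, which had a rho of -0.254 with GC content. Such a deviation would also lower GC-rich ORFs in poly(A)-selected against unselected. There the rho with GC content was between -0.102 and 0.054 within quintiles of coding length. Other steps of the RiboMinus library's preparation, such as fragmentation or amplification, were not tested and stay open. No biological explanation was tested.

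Cell wall protein mRNAs were lower after RiboMinus treatment. Their GC content alone is argued against, since the list's median was at percentile 0.09 of random lists matched on GC. A deviation of the unselected library stays open, since the list was at percentile 1.61 of GC-matched lists after oligo(dT) selection as well. Between the poly(A)-selected and RiboMinus libraries it was at 34.8 of GC-matched, 85.9 of expression-matched and 94.15 of length-matched lists. There 12 ORFs were at least 1.5-fold higher and 2 lower. CCW12 and CWP2 had 0.65 and 0.79 after oligo(dT) selection against -2.82 and -2.23 after RiboMinus treatment. No biological explanation was tested.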
